A study of Homo sapiens with 6 samples.

How the data were processed

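Total RNA of 6 SH-SY5Y samples was measured on 1-colour oligonucleotide arrays, 3 after transfection with anti-miR-137 and 3 after transfection with a control anti-miR. Per the labels' protocols, cells were transfected with 15 pM anti-miR 24 hours after seeding, RNA was isolated 72 hours after transfection, and 100 ng of it were amplified and labelled with biotin. Per the submitters' processing notes the arrays were processed with RMA in R 3.0.1. The deposited values are log2 values per probe set: RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a probe set on a log2 scale, so that only relative differences between arrays remain, and a shift of all transcripts together could not be seen. The values ran from 2.98 to 15.3 with array medians within 0.040 of each other, and the scanner files were not used here. All 6 columns were mapped to samples by their labels.

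The file held 49495 probe sets, of which 102 were the manufacturer's controls. Of the others, 45278 had 1 gene symbol in the platform annotation used here, 1333 had several and 2782 had none. For 45208 of the 45278, the gene identifier was found in the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Only probe sets with 1 symbol were used for genes. Older symbols in the gene lists were replaced by current ones through the same table (*RIGI* for DDX58, for example). No genome positions are given, because the annotation used here has none tied to the probe sets.

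A probe set was kept when its mean over all 6 arrays reached the 40th percentile of all probe set means, a log2 value of 5.69, and each gene was represented by its probe set with the highest mean, which left 12639 genes from 27514 probe sets. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are anti-miR-137 over control on the log2 scale. Before the data were examined, 19 gene lists were fixed: reported miR-137 targets, schizophrenia risk loci, 2 synaptic lists, neuronal differentiation, 3 cell identity lists, 2 cell cycle lists, PRC2 and LSD1-CoREST, and 8 stress, metabolic and signalling lists. They were written from general knowledge of the field. Each was tested with camera (preset correlation of 0.01), adjusted over the 19 lists, and again with an estimated correlation and with fry. The percentile of a list's median came from 10000 random lists of the same size matched on mean level in 20 bins. The mean deviation of a list per array was compared by an exact permutation test.

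Also fixed beforehand were the genes to be named: for each direction the 12 genes past the threshold with the largest changes or, with fewer than 8 past it, the 8 genes with the smallest unadjusted p; 4 genes with the smallest p from each list that passed and from the target and risk locus lists; and 2 from each other list. The alternatives tried were no filter and a stricter one at the 60th percentile, averaging probe sets, leaving out probe sets with suffixes that mark possible cross-hybridisation, quantile normalization or median centring on top, a variance prior with trend, array weights, the replicate number as a block, the RNA integrity number as a covariate, and leaving out each array. Cyclic loess normalization was added after seeing the data. The main steps were tested on simulated data with the means and spreads of the 12639 genes and 200 changed genes in 20 simulations: on average 10.7 unchanged genes were called per simulation, and camera called 0% of unshifted lists and 100% of lists of 33 genes shifted by -0.1 log2 units, with members simulated as independent. A planned comparison of mRNAs with and without miR-137 seed sites was not run, since 3' UTR sequences were not used here. No pair of arrays held the same values: pairs differed by a root mean square of 0.13 to 0.24 log2 units over the 12639 genes.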

Results

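Gene expression was profiled in SH-SY5Y cells, an established line derived from a human neuroblastoma and widely used as a neuronal cell model. The cells were transfected with an inhibitor of miR-137 (anti-miR-137) or with a control anti-miR, and total RNA was taken 72 hours later. MiR-137 is a brain-enriched microRNA, and its gene lies in a locus associated with schizophrenia. The stated purpose was to find mRNAs that change when miR-137 is inhibited and could be new targets of it. Each group held 3 arrays, numbered 1 to 3 in both groups. Each array carried 49393 probe sets besides the control probe sets, with a median log2 value between 6.39 and 6.43. The RNA integrity numbers lay between 9.5 and 9.8. The labels name the replicates but not whether they came from separate cultures, so the p-values measure the spread between these arrays, which may be partly technical. The number of arrays limits the precision of every value. No probe set used here was named for the miR-137 gene or its host transcript, so the inhibition itself was not checked.

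No mRNA differed between anti-miR-137 and control cells after correction for multiple testing: 0 of 12639 genes had an adjusted p under 0.05 in limma, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 335 genes, 209 with higher and 126 with lower values in the anti-miR-137 arrays, where 632 would be reached by chance among independent genes. That count depended on the model. It was 815 with the replicate number as a block and 1091 with array weights, with 0 genes past the adjusted threshold in both. No gene differed by 1.5-fold or more. The log2 fold changes had a median of 0.0033, with -0.14 at the lower and 0.14 at the upper end of the range that leaves out the outermost 5% on each side. The values of the groups did not overlap for 930 genes (7.36%), where chance gives 10% for 3 arrays against 3. The median half-width of the 95% confidence interval of a gene's log2 fold change was 0.19, and for 12066 genes (95.5%) the interval lay within 0.5 log2 units of 0. In data simulated from these arrays with 200 changed genes, the same test recovered 80.5% of changes of 0.5 log2 units and 98.8% of changes of 1 log2 unit. The simulated genes varied independently of each other, and many changed genes make the adjusted threshold easier to reach. These shares therefore do not tell what would be found if only a few genes changed.

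The genes with the smallest unadjusted p among higher values were all among the dimmest 20% of the 12639 tested genes, and none passed the test. *OR5A2*, an olfactory receptor gene, measured 6.15 ± 0.081 (SD, n = 3) in anti-miR-137 cells and 5.77 ± 0.040 (n = 3) in control cells, a log2 fold change of 0.38 with a standard error of 0.065. *DCHS1*, a large cadherin of the Fat and Dachsous pathway, measured 6.92 ± 0.026 and 6.60 ± 0.032, a log2 fold change of 0.33. *SLC37A2*, a sugar-phosphate transporter, had the greatest increase in value of all genes at 0.48 log2 units with a standard error of 0.10. *LOC613206* (0.36), the transcription factor *SOX13* (0.32), *AMBP* (0.30), the oligodendrocyte lineage factor *OLIG2* (0.27) and the adrenergic receptor *ADRA1D* (0.24) completed the 8. The other probe sets of *SLC37A2* gave between -0.02 and 0.09 log2 units, and the 3 others of *SOX13* gave 0.08 to 0.14.

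Among lower values, *ZNF91*, a zinc finger repressor of transposable elements, measured 9.26 ± 0.098 in anti-miR-137 cells against 9.58 ± 0.074 in control cells (SD, n = 3 each), a log2 fold change of -0.32 with a standard error of 0.074. *GK5* (-0.29), the signalling ligand *WNT3* (-0.29), *MICU3*, a regulator of mitochondrial calcium uptake (-0.28), *ENTPD7* (-0.27), the glycolytic regulator *PFKFB2* (-0.27), *AHNAK2* (-0.24) and *C5orf63* (-0.24) followed, and each had an adjusted p of 1.00 in limma. Probe sets of one gene disagreed in several cases. All 5 other probe sets of *PFKFB2* (0.04 to 0.19), both others of *ENTPD7* (0.05 to 0.17) and the other probe set of *ZNF91* (0.04) had higher values in anti-miR-137 cells. Outside the rule for named genes and chosen after its value was seen, *CFAP43* had the greatest decrease in value, -0.56 log2 units with a standard error of 0.17.

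**Figure D1:**
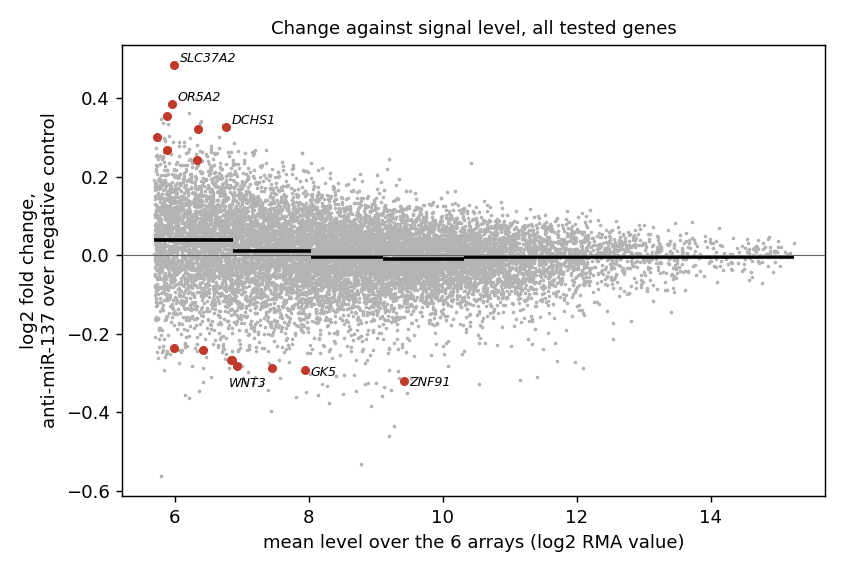
Log2 fold change of each of the 12639 tested genes (anti-miR-137 over negative control, vertical axis) against its mean log2 RMA value over the 6 arrays (horizontal axis). Red points are the 16 genes with the smallest unadjusted p, 8 in each direction, and black bars are medians of 5 groups of equal size by level, 0.038 in the dimmest and -0.0042 in the brightest.

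Fold changes were related to signal level. In the dimmest 20% of the tested genes the median log2 fold change was 0.038 and 64.3% of genes had higher values in anti-miR-137 cells. In the brightest 20% the median was -0.0042 and 46.6% had higher values. Of the 209 genes with higher values at an unadjusted p under 0.05, 129 were in the dimmest 20% and 1 in the brightest 20%.

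No increase was found among mRNAs reported as miR-137 targets. All 52 listed mRNAs had a probe set, and 39 were kept by the filter on dim probe sets. None of these 39 passed the test in limma, over all genes or adjusted over the list alone. Of them, 14 had higher and 25 lower values in anti-miR-137 cells. Without the filter, the mean log2 fold change over all 52 was -0.0043 (adjusted p = 0.40, limma set test). The lower mean given below therefore rests on the 39 kept mRNAs. *EZH2*, the catalytic subunit of the PRC2 histone methyltransferase, had a log2 fold change of -0.09 (95% confidence interval -0.40 to 0.22). *KDM1A*, the histone demethylase LSD1, had 0.02 (-0.12 to 0.16), the cell cycle kinase *CDK6* -0.01 (-0.23 to 0.20), and *MIB1*, a ubiquitin ligase of the Notch pathway, -0.12 (-0.29 to 0.055); these 4, the release machinery genes below and *TCF4* were named as well-known targets after their values were seen. The vesicle release genes *SYT1* (-0.01), *NSF* (0.03) and *CPLX1* (-0.0031) and the transcription factor *TCF4* (0.0025) also had intervals that included 0. The smallest p in the list belonged to *GLIPR1* (-0.16), the apoptosis inhibitor *XIAP* (-0.11), *ZNF804A* (-0.10) and the mitophagy receptor *BNIP3L* (-0.09). *GLIPR1* was dim, with a mean log2 value of 5.87. Only 3 of its 5 other probe sets also had lower values, and the 5 ranged from -0.13 to 0.18. For 35 of the 39 mRNAs the upper bound of the interval was under 0.3 log2 units. The list mean was -0.029 ± 0.073 (SD over the 39 genes), and limma's set test gave an adjusted p of 0.19 with its preset correlation. The same set test gave 0.072 with averaged probe sets and 0.081 with the replicate number as a block. It gave 0.43 with the stricter filter and 0.61 with an estimated correlation. The direction was lower in each of these, and none passed.

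**Figure D2:**
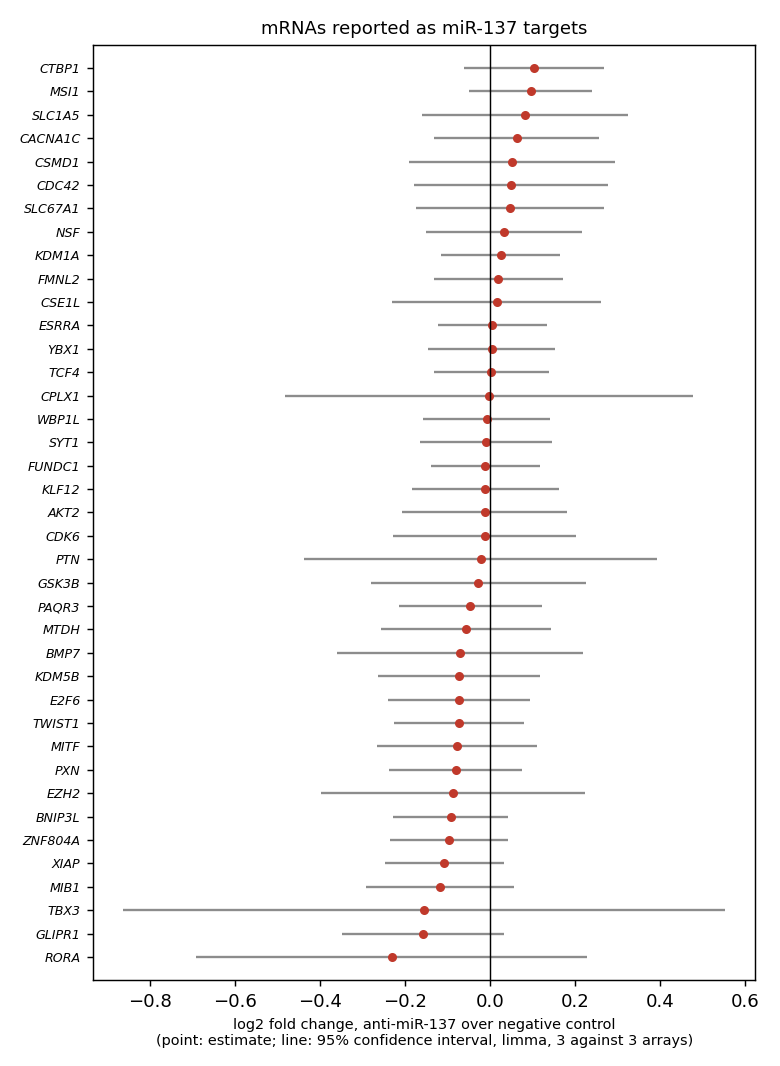
Log2 fold change (horizontal axis) of each of the 39 tested mRNAs reported as miR-137 targets (rows), anti-miR-137 over negative control, with 95% confidence intervals from limma on 3 arrays per group. All 39 intervals include 0, and 25 of the 39 estimates are below it.

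Genes at schizophrenia risk loci did not pass as a group. Of 54 tested genes, 24 had higher and 30 lower values, and none passed the test over all genes or adjusted over the list alone. The list mean was -0.016 (adjusted p = 0.50, limma set test). *TRIM26* measured 8.03 ± 0.063 in anti-miR-137 cells and 7.86 ± 0.018 in control cells (SD, n = 3 each), a log2 fold change of 0.16 with a standard error of 0.059. *KCTD13* (0.11), the transcription factor *ZEB2* (-0.23) and the endocytic adaptor *SNAP91* (-0.16) had intervals that included 0.

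Synaptic and neuronal genes did not pass as groups with treatment group as the only term. Of 42 presynaptic vesicle release genes, 19 had higher and 23 lower values, with a list mean of -0.027 (adjusted p = 0.19 in limma's set test). The presynaptic adhesion gene *NRXN2* (-0.18) and the calcium sensor *SYT7* (-0.17) had the smallest p. Of 28 postsynaptic receptor and scaffold genes, 15 had higher values, with a mean of 0.0011 (adjusted p = 0.87). The scaffold genes *HOMER2* (0.27) and *DLG3* (0.15) led that list. Of 47 genes of neuronal differentiation and the cytoskeleton, 33 had lower values, with a mean of -0.035 (adjusted p = 0.26). The neurotrophin receptor *NTRK3* (0.21) and the neuronal splicing factor *RBFOX3* (0.26) had the smallest p there, and 2 of the 3 other probe sets of *NTRK3* went the other way. No gene of these 3 lists passed over all genes or adjusted over the list alone. The neuronal differentiation list stood at -0.092 and -0.072 log2 units from its 6-array mean in the replicate 1 arrays and at 0.085 and 0.13 in the replicate 3 arrays (anti-miR-137 first in each case). With the replicate number as a block, limma's set test gave this list an adjusted p of 0.040 with its preset correlation.

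Markers of cell identity gave no call in 1 direction as groups. The noradrenergic neuroblastoma list, which holds the sympathetic transcription factors and catecholamine enzymes, had 11 of 38 genes with higher and 27 with lower values and a mean of -0.018 (adjusted p = 0.19, limma set test). *ZNF536* (0.11) and *DLK1* (-0.07) had its smallest p. The mesenchymal, substrate-adherent neuroblastoma list had a mean of 0.011 (adjusted p = 0.68), with *SIX4* (0.26) and *NOTCH3* (0.17) leading its 33 genes. Of 7 tested glial and Schwann cell markers, 5 had higher values, with a mean of 0.085 (adjusted p = 0.14). The mean was 0.0099 (adjusted p = 0.86) without probe sets that may cross-hybridise and 0.023 (adjusted p = 0.65) over 16 genes without the filter on dim probe sets. The mixed test of fry, which asks for changes in either direction, gave this list an adjusted p of 0.0013, and its directional test gave 0.37. *OLIG2* and *GFAP*, an astrocyte intermediate filament, were 2 genes past the threshold when adjusted over the list alone (smallest adjusted p 0.018, limma), and neither passed over all genes. The log2 fold change of *GFAP* was 0.20 on its brightest probe set, while 5 of its 7 other probe sets had lower values in anti-miR-137 cells, down to -0.32.

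Cell cycle genes varied more between replicate numbers than between treatments. The 47 genes of G1/S and DNA replication had a mean log2 fold change of 0.044 (adjusted p = 0.23 in limma's set test), and the 55 genes of G2/M and mitosis one of 0.025 (adjusted p = 0.66). No member passed over all genes or adjusted over the list alone. In the G1/S list, *CCND3*, a cyclin of the G1 phase, had a log2 fold change of 0.14 and the primase subunit *PRIM1* one of 0.13. In the G2/M list, the phosphatase *CDC25C* had 0.09 and the topoisomerase *TOP2A* -0.15. The G1/S list stood at -0.17 in the anti-miR-137 and -0.26 in the control array of replicate 1, at -0.035 and -0.038 in those of replicate 2, and at 0.27 and 0.23 in those of replicate 3. With the replicate number as a block, limma's set test gave the G1/S list an adjusted p of 0.0038 with its preset correlation. With an array left out, the sign of both lists depended on which one: with the preset correlation of 0.01, the G1/S mean was -0.076 (adjusted p = 0.029) without control replicate 1, -0.082 (0.016) without anti-miR-137 replicate 3, 0.14 (1.9e-05) without anti-miR-137 replicate 1 and 0.17 (4.4e-09) without control replicate 3. Leaving out an array also unbalances the replicate numbers between the groups, so these means carry part of the difference between numbers. The correlation between G1/S members estimated from the 6 arrays was 0.81, and the list with all arrays had an adjusted p = 0.91 with an estimated correlation. The PRC2 and LSD1-CoREST list, which includes *EZH2* and *KDM1A*, had 11 higher and 12 lower values, a mean of -0.0016 (adjusted p = 0.68) and no gene past the test. Its leading genes were *PHF1* (0.20) and the deacetylase *HDAC1* (-0.08), whose 2 other probe sets had higher values (0.04 and 0.12).

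**Figure D3:**
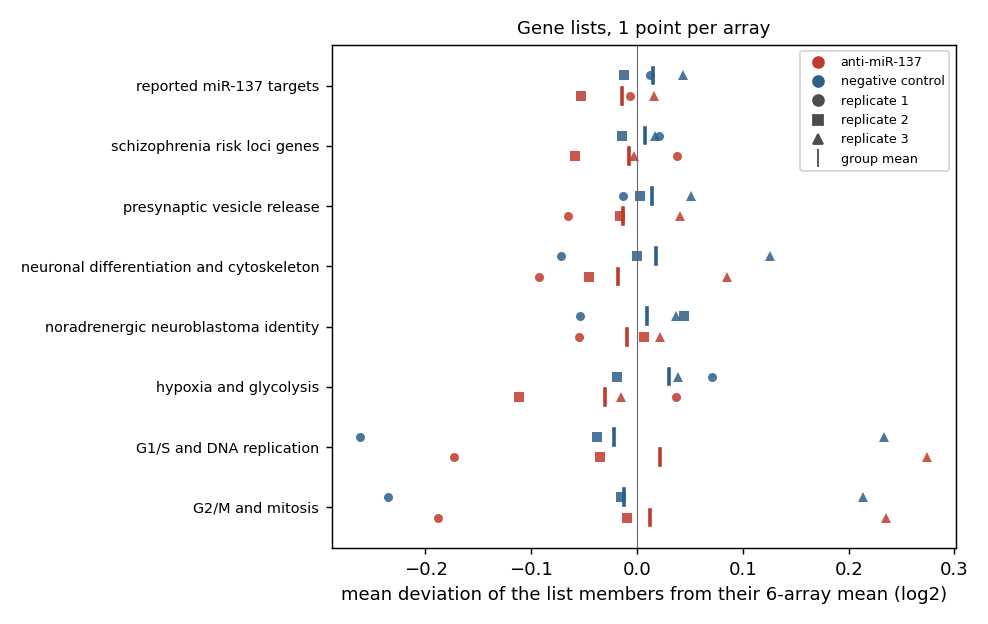
Mean deviation of the members of 8 gene lists (rows) from their 6-array mean, in log2 units (horizontal axis), with 1 point per array, colour for treatment, shape for replicate number and a vertical bar for each group's mean. The G1/S list runs from -0.26 to 0.27, with replicate 1 arrays low and replicate 3 arrays high in both groups, and the hypoxia and glycolysis list has its lowest value, -0.11, in anti-miR-137 replicate 2.

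Hypoxia and glycolysis genes were the 1 list of 19 that passed the set test with group as the only term. Of its 33 genes, 26 had lower and 7 higher values in anti-miR-137 cells, with a mean log2 fold change of -0.060 ± 0.084 (SD over genes), and limma's set test gave an adjusted p of 0.0096 with its preset correlation. The call did not hold with a correlation estimated from the arrays (adjusted p = 0.61 with an estimated correlation). No single gene passed, over all genes or adjusted over the list alone. *PDK1*, a kinase that restrains pyruvate oxidation, measured 9.79 ± 0.059 against 9.99 ± 0.062 (SD, n = 3 each), a log2 fold change of -0.20, and the collagen prolyl hydroxylase subunit *P4HA1* had -0.17. *PFKFB4* (-0.12) and the hexokinase *HK2* (-0.12) followed, each with other probe sets that went the other way. The list lay at 0.037, -0.11 and -0.015 in the 3 anti-miR-137 arrays and at 0.071, -0.019 and 0.038 in the 3 control arrays. An exact two-sided permutation test of these 6 values gave p = 0.40, and 3 against 3 allows no p under 0.1. That test ignores the replicate numbers, and within each number the anti-miR-137 array had the lower value. This order is not particular to the list. The reported target, presynaptic, neuronal differentiation, noradrenergic and cholesterol lists were also lower in the anti-miR-137 array of every number. The glial, G1/S, G2/M and interferon lists were higher in it in every number. With the replicate number as a block, limma's set test gave an adjusted p of 0.0015 with its preset correlation. Without anti-miR-137 replicate 2 the mean was -0.019 (adjusted p = 0.25), and without control replicate 3 it was -0.056 (adjusted p = 0.10); the call also ended when all probe sets of a gene were averaged (-0.043, adjusted p = 0.072) and when probe sets that may cross-hybridise were left out (-0.058, adjusted p = 0.18).

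The stress, metabolic and signalling lists that remained did not pass the set test in limma, and no member passed over all genes or adjusted over its list alone. The p53 and apoptosis list had 9 higher and 25 lower values among 34 genes, a mean of -0.033 (adjusted p = 0.19), and *GDF15*, a stress cytokine (0.26), and *MDM2*, the p53 ubiquitin ligase (-0.23), with the smallest p; 3 of the 4 other probe sets of *GDF15* had lower values in anti-miR-137 cells, down to -0.11. The interferon and RNA sensing list had a mean of 0.043 (adjusted p = 0.19), led by *IFITM3* (0.17) and the RNA sensor *RIGI* (0.22). The ER stress and amino-acid response list had a mean of -0.018 (adjusted p = 0.26), led by the serine synthesis enzyme *PSAT1* (-0.16) and *VLDLR* (-0.16). The cholesterol synthesis list had a mean of -0.011 (adjusted p = 0.64), led by *STARD4* (-0.14) and *MVD* (0.11). The Notch and Wnt list had a mean of 0.0035 and a median of -0.016 (adjusted p = 0.88), led by *NOTCH1* (0.17) and *AXIN1* (0.20). The PI3K, AKT and mTOR list had a mean of 0.0012 and a median of -0.0093 (adjusted p = 0.87), led by *PIK3CB* (0.26) and *IRS1* (0.14). The immediate early genes had a mean of 0.0039 and a median of -0.0013 (adjusted p = 0.87), led by *KLF2* (0.16) and *SPRY4* (0.17). Over the 19 lists, exact two-sided permutation tests of the 6 array values gave p between 0.20 and 1.0.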

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

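The count of 0 genes past the adjusted threshold was the same under every alternative run, including an adjusted p under 0.1, each kept probe set on its own (27514 tested), cyclic loess normalization (chosen after seeing the data) and each left-out array (0 to 0); counts at an unadjusted p under 0.05 were 335 in the main setting, 1091 with array weights and 198 to 587 with an array left out. Same-numbered arrays deviated together in replicates 1 and 3 (correlations of deviations 0.55 and 0.65) but not clearly in replicate 2 (0.073), and every pair had to be over 0.1 for the numbers to be taken as pairs, so they were not. Differences between replicate numbers therefore remained in the spread that the main tests and intervals used. As a hint from the data, every array correlated best with its own number by its values (0.9964 for replicate 2, 0.9961 for anti-miR-137 replicate 2 with anti-miR-137 replicate 1). By deviations anti-miR-137 replicate 2 was closest to control replicate 1 (0.16). With the replicate block 0 genes passed (815 at an unadjusted p under 0.05). Hypoxia and glycolysis (-0.060, adjusted p = 0.0015), G1/S (0.044, adjusted p = 0.0038) and neuronal differentiation (-0.035, adjusted p = 0.040) then passed the set test with its preset correlation of 0.01. Without the block the correlations estimated for the last 2 lists were 0.81 and 0.22, and both had an adjusted p = 0.91 with an estimated correlation. With the block these correlations were 0.033 and -0.021, and 0.0076 for hypoxia and glycolysis. The set test for treatment was not run with the block and an estimated correlation together. The values without the block therefore do not settle these calls. The hypoxia and glycolysis list kept its direction in every alternative but lost its call with averaged probe sets (-0.043), without cross-hybridising probe sets (-0.058), with an estimated correlation and with fry (-0.060 in both, adjusted p = 0.61 and 0.90), and without anti-miR-137 replicate 2 (-0.019, adjusted p = 0.25) or control replicate 3 (-0.056, adjusted p = 0.10); it ranged from -0.094 to -0.019 with an array left out and was -0.12 (adjusted p = 0.00014) with the RNA integrity number as a covariate. With the RNA integrity number as a covariate G1/S (0.16) and G2/M (0.14) passed with the preset correlation, while without the covariate G2/M had an estimated correlation of 0.87 and an adjusted p = 0.92 with an estimated correlation (G1/S as above); the number differs little between arrays, so this fit leans on anti-miR-137 replicate 1. For calls gained or lost otherwise the cause was not tested.

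List means whose set test changed direction, none of them past the threshold: no filter, Notch and Wnt -0.00053 and immediate early genes 0.0093; stricter filter, PI3K -0.017 and immediate early -0.040; averaged probe sets, mesenchymal -0.0013 and Notch and Wnt -0.0014; no cross-hybridising probe sets, mesenchymal -0.022, Notch and Wnt -0.0047 and immediate early -0.029; quantile normalization, immediate early 0.0076; array weights, G2/M -0.0036, PI3K -0.012 and immediate early -0.014; replicate block, Notch and Wnt 0.0035; RNA integrity, neuronal differentiation 0.0038, mesenchymal -0.067, ER stress 0.032, cholesterol 0.045, Notch and Wnt -0.023 and immediate early 0.0080; cyclic loess, immediate early -0.00027. With an array left out, between 0 (without anti-miR-137 replicate 2) and 11 lists (without control replicate 1) passed, against 1 in the main setting, and the list means ranged as follows: reported targets -0.045 to -0.010, risk loci -0.039 to 0.0098, presynaptic -0.055 to -0.0014, postsynaptic -0.0096 to 0.014, neuronal differentiation -0.087 to 0.018, noradrenergic -0.050 to 0.0047, mesenchymal -0.050 to 0.046, glial 0.066 to 0.11, G1/S -0.082 to 0.17, G2/M -0.087 to 0.14, PRC2 and LSD1 -0.025 to 0.014, p53 -0.055 to -0.013, interferon -0.0089 to 0.095, ER stress -0.073 to 0.028, cholesterol -0.053 to 0.030, Notch and Wnt -0.017 to 0.026, PI3K -0.021 to 0.013, immediate early genes -0.0060 to 0.019. Of 963 results for the 59 named genes under alternatives, 956 kept their direction and 0 passed the threshold. The 7 that reversed came from other probe sets: averaged, *GFAP* -0.064, *HDAC1* 0.019 and *PFKFB4* 0.062; without cross-hybridising probe sets, *GFAP* -0.32, *HDAC1* 0.12, *SNAP91* 0.13 and *PSAT1* 0.016. The planned seed-site comparison and its alternatives were not run.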

Other observations

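The tests on replicate number, on the level trend of the hypoxia list and on RNA integrity were chosen after their results had been seen in part, as were the counts of genes over splits of the arrays; the splits for the hypoxia list and the tests of correlated list members, of background signal and of other matchings of the arrays were written down before their results. The arrays differed far more by replicate number than by treatment. In an additive model of treatment and replicate number (limma, 2 arrays per number), 320 genes had an adjusted p under 0.05 for replicate number, against 0 for treatment, and the first principal component (50.1% of the variance) placed both replicate 1 arrays at one end and both replicate 3 arrays at the other. *NELL2*, a secreted neuronal glycoprotein, measured 6.64 and 6.69 in the anti-miR-137 and control arrays of replicate 1, 8.26 and 8.15 in those of replicate 2 and 8.54 and 8.70 in those of replicate 3 (adjusted p = 0.0076). *GRIP1*, a scaffold protein of glutamate receptors, measured 8.57 and 8.62, 8.49 and 8.44, and 6.77 and 6.91 (adjusted p = 0.0076). The neuropeptide gene *VIP* differed by 1.71 log2 units between replicates 3 and 1, the neurofilament gene *NEFM* by 1.23, the Wnt receptor *FZD5* by 1.04, the interferon-induced *USP18* by -1.51 and the stem cell marker *LGR5* by -0.86, all past the same test.

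Of the 47 G1/S genes, 23 differed by replicate number and all 23 were higher in replicate 3 than in replicate 1, with *UHRF1*, a DNA methylation maintenance factor (0.78), and the thymidine kinase *TK1* (0.72) as examples; of the 55 G2/M genes 17 did, also all higher, with the mitotic transcription factor *FOXM1* (0.82) and the cohesion factor *CDCA5* (0.67) among them. List means of replicate 3 minus replicate 1 were 0.47 for G1/S, 0.44 for G2/M, 0.19 for neuronal differentiation, 0.19 for ER stress and amino-acid response, 0.14 for cholesterol synthesis, 0.086 for presynaptic genes, -0.14 for the mesenchymal list and -0.18 for interferon genes; these 8 passed camera with its preset correlation, and none did with an estimated one (smallest adjusted p = 0.12 with an estimated correlation), a fit with 2 residual degrees of freedom. Against chance pairs, the 5 other one-to-one matchings of treated and control arrays gave at most 1 gene past the threshold where the labelled numbers gave 320. A trend with signal level is argued against by level-matched random lists, among which the cell cycle lists stood at the 100th percentile. RNA integrity as the whole cause is argued against by arrays of equal integrity number: their largest difference in the G1/S list was 6.06 times the largest difference within a replicate number, and the ratio for G2/M was 9.85. No biological explanation was tested, since the labels name none for the replicate numbers; a separate culture, passage or processing day for each number stays open, and may be read as a hypothesis only.

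The lower hypoxia and glycolysis list was weighed as a second pattern. A trend with signal level is argued against: the list median stood at percentile 0.06 of level-matched random lists, and its adjusted p was 0.030 after cyclic loess. Members that vary together between arrays of either group remain a candidate explanation, since 2 of the 9 other splits of the 6 arrays also gave a camera p under 0.05; the real p of 0.00051 was reached or passed in 3 of the 10 splits, with 0.00021 as the smallest of the others. The 2 other splits with a camera p under 0.05 each put both replicate 2 arrays on one side, while the real split held every replicate number on both sides. Those 2 splits therefore also carried differences between replicate numbers, which the real split balances. They cannot tell members that vary together within a number from such differences. The estimated correlation between members was 0.10 with group as the only term and 0.0076 with the replicate number as a block. With 10 splits no share under 0.05 is possible. An effect of anti-miR-137 stays open and untested beyond this.

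The higher values of dim genes in anti-miR-137 arrays were weighed as the last pattern. Over the 6 arrays, the mean deviation of the dimmest 20% of the tested genes followed the mean of the 23 background control probe sets (Pearson r = 0.97, exact permutation p = 0.0069; Spearman rho = 0.83, exact permutation p = 0.058; r = 0.97 without the 2 arrays farthest from the median background; 1 relation was computed, so adjustment leaves these p as they are). The background mean was 5.12, 5.12 and 5.08 in the anti-miR-137 arrays and 5.13, 5.05 and 5.00 in the control arrays. Unspecific background signal that differs between arrays is therefore a candidate explanation for the shift of dim genes as a group, and an effect of treatment on dim transcripts was not separated from it. Whether it accounts for any single dim gene was not tested.

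Over the 10 splits of the arrays into 3 and 3, 10 gave as many genes past the adjusted threshold as the real one, which gave 0, and the highest other count was 0; at an unadjusted p under 0.05, 7 splits including the real one reached its 335 genes, and the highest other count was 2623. The split with 2623 set both replicate 1 arrays and anti-miR-137 replicate 2 against the rest and so followed the replicate numbers. Since the real count past the adjusted threshold was 0, every split had to reach it, and that comparison can show nothing. The splits are also too few for a share under 0.05. Outside the gene table, 0 of 4115 probe sets with no or several gene symbols had an adjusted p under 0.05 in limma (161 at an unadjusted p under 0.05).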
